A study of Mus musculus with 9 samples.

How the data were processed

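Gene expression was measured in hindlimb skeletal muscle of neonatal mice aged 2, 7 and 14 days (P2, P7 and P14), with 3 arrays at each age and 9 in all. The sources name the 3 samples of an age as biological replicates and give the strain as mixed; whether a replicate is 1 animal or a pool is not given in the sources used here. Total RNA was extracted with Trizol, and biotinylated cRNA was made from 6 ug of it by the manufacturer's standard procedure. The array platform and the genome build behind the probe sets are not given in the sources used here.

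The deposited table holds 1 log2 intensity for each of 41345 probe sets on each array. RMA and Partek are named in the submitters' processing notes, with no version and no settings. RMA corrects background, normalises between arrays and summarises probes to a log2 value per probe set, so the log2 base is taken from RMA and is not written in the table. The arrays had medians of 3.29 to 3.36 and highest values of 12.9 to 13.5, with no missing value. The raw probe intensities were not used here.

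Probe sets were named from a table that pairs probe set numbers with gene symbols and Entrez numbers. It lists 25335 of the 41345 probe sets, 23521 with 1 symbol and 1814 with several; the other 16010 are not listed there, so they are unnamed here, which does not mean that they lack a gene. Probe sets with several symbols and those not listed were left out. Of the 1-symbol probe sets, 23328 matched a gene of the RefSeq table of assembly GRCm38.p6 by Entrez number, and that table was used only for names and for the order of neighbouring genes. For each gene the probe set with the highest mean over the 9 arrays was kept, which gave 22180 genes, 1082 of them with more than 1 probe set. No filter on dim genes was applied. As a measure of background, chosen after the values were seen, 1425 smell and taste receptor genes had a 95th percentile of 3.40, and 13420 genes (60.5%) had a mean above it in at least 1 age. The median of all genes was 3.65. Probe sets for microRNA genes read signal from the precursor or host transcript, not the mature microRNA.

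Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per age and all 9 arrays sharing 1 estimate of the spread, followed by empirical Bayes moderation. P7 was compared with P2, P14 with P7, and P14 with P2. A contrast of the later interval minus the earlier one (P14 minus P7, less P7 minus P2) tested whether the change differed between the intervals, which last 7 and 5 days, and a moderated F-test asked for any change over the 3 ages. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over all 22180 genes, and genes with an adjusted p under 0.05 were counted as changed. The count with at least a 2-fold change is given beside it. Errors of log2 changes are standard errors (SE) of the moderated fit, and errors of values at an age are standard deviations (SD) of 3 arrays. The p-values measure the spread between these samples, part of which can be technical, and the number of arrays limits the precision. The overlap of the intervals was set against independent lists and against 100 simulated sets of unchanged groups that share the P7 arrays.

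Fixed gene lists, 38 of which had at least 5 measured genes, were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 38 lists, and again with an estimated correlation and with fry. The lists were developmental sarcomere isoforms, adult fast sarcomere and calcium isoforms, slow fibre isoforms, sarcomere scaffold and Z disc, dystrophin complex, excitation-contraction coupling, neuromuscular junction, myogenic regulators and satellite cells, myoblast fusion, Notch pathway, cell cycle, imprinted growth genes, insulin-like growth factor axis, interstitial matrix, basement membrane, oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation, glycolysis and glycogen, ribosomal proteins, ribosome biogenesis, protein breakdown and autophagy, splicing regulators of muscle, circadian clock, interferon-stimulated genes, antigen presentation and immediate early genes. Markers of other cell types covered endothelial cells, pericytes and smooth muscle, fibroblasts and fibro-adipogenic cells, tendon, adipocytes, macrophages, lymphocytes, neutrophils and granulocyte precursors, erythroid cells, Schwann cells and nerve, cartilage and bone, and epidermis. Of 688 list genes 624 (90.7%) were measured, 12 of them under a synonym. The erythroid list had 4 measured genes and was not tested.

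The genes named in the text follow a rule. For each pair of ages these are the 6 largest rises and the 6 largest falls among changed genes whose 3 arrays at one age all lie above or all below the 3 of the other, with a mean in the brighter age above the median of all genes, passing over symbols that are only clone or locus numbers. For each list and pair of ages up to 4 changed members with the smallest adjusted p were added, and Myh3, Myh8, Myh1, Myh2, Myh4, Myh7, Chrng, Chrne, Pax7, Myod1, Myog, Igf2, H19, Mki67, Col1a1 and Col3a1 were named whatever their values. H19 was not measured by a probe set of its own. Genes outside this rule are given as chosen after their values were seen.

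The alternatives were centring each array on its median, quantile normalization and cyclic loess of the deposited values, filters on dim genes at the median and the 25th percentile of all probe sets, the mean of a gene's probe sets, all probe sets, a trended prior with and without robust estimation, no moderation, array weights, only the 2 ages compared, the replicate number as a block, leaving out each array in turn, and for lists the estimated correlation, fry and camera on ranks. The comparisons, lists, named-gene rule and these alternatives were chosen before the data were examined. An alternative restricted to probe sets without cross-hybridising identifier endings was not run, since the identifiers carry no such endings. Added after the values were seen were Xist as a covariate, the level of neutrophil and erythroid markers as a covariate, and only genes above the receptor genes. The procedure was tested on simulated data of the same size for P7 against P2, with known shifts added to some genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.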

Results

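RNA from mouse hindlimb skeletal muscle was profiled on arrays at P2, P7 and P14, with 3 biological replicates at each age. Replicates correlated at 0.953 to 0.964 at P2, 0.967 to 0.974 at P7 and 0.981 to 0.984 at P14, across the genes, which are not independent of each other. The median SD of a gene among the 3 arrays was 0.251 at P2, 0.203 at P7 and 0.163 at P14 on the log2 scale. On the first principal component, which held 38.2% of the variance, the P2 arrays lay at -46.2, -28.8 and -23.7, the P7 arrays at -2.38, -5.61 and -3.48, and the P14 arrays at 36.8, 38.4 and 34.9. The second component (14.3%) set P2 replicate 2 at -33.2, apart from the other P2 arrays at 21.5 and 27.8. Each replicate array had a median of 3.29 to 3.36, and the number of arrays limits the precision of every value that follows.

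The first comparison asked which transcripts changed in the first postnatal week, from P2 to P7. Several adult fast contractile transcripts rose and several developmental ones fell. Parvalbumin (Pvalb), a calcium buffer of fast fibres, rose 9.04-fold (log2 change 3.18 ± 0.41, SE; 6.24 ± 1.23 at P2 and 9.42 ± 0.20 at P7, SD, n = 3; adjusted p = 0.00519). Myh4, Myh1 and Myh2 encode the adult fast myosin heavy chains; they rose 17.0-fold (log2 4.08 ± 0.79), 7.03-fold (2.81 ± 0.42) and 4.90-fold (2.29 ± 0.43). The embryonic myosin Myh3 fell and was 3.74-fold lower at P7 (log2 -1.90 ± 0.32), and the perinatal myosin Myh8 was 2.11-fold lower (-1.08 ± 0.16). The slow myosin Myh7 had a log2 change of 0.10 ± 0.31 and was not called (adjusted p = 0.923). Leaving out single arrays ended all 5 myosin calls. Myh4 lost its call without any 1 of the P7 or P14 arrays (adjusted p up to 0.153, without P7 replicate 3), and its log2 change was 2.67 without P2 replicate 1. Myh1 lost it without any P7 array (up to 0.0637), Myh2 without any array but P2 replicate 3 (up to 0.131), Myh3 without P2 replicate 1 or P7 replicate 3 (up to 0.0890) and Myh8 without P7 replicate 3 (0.0610).

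**Figure D1:**
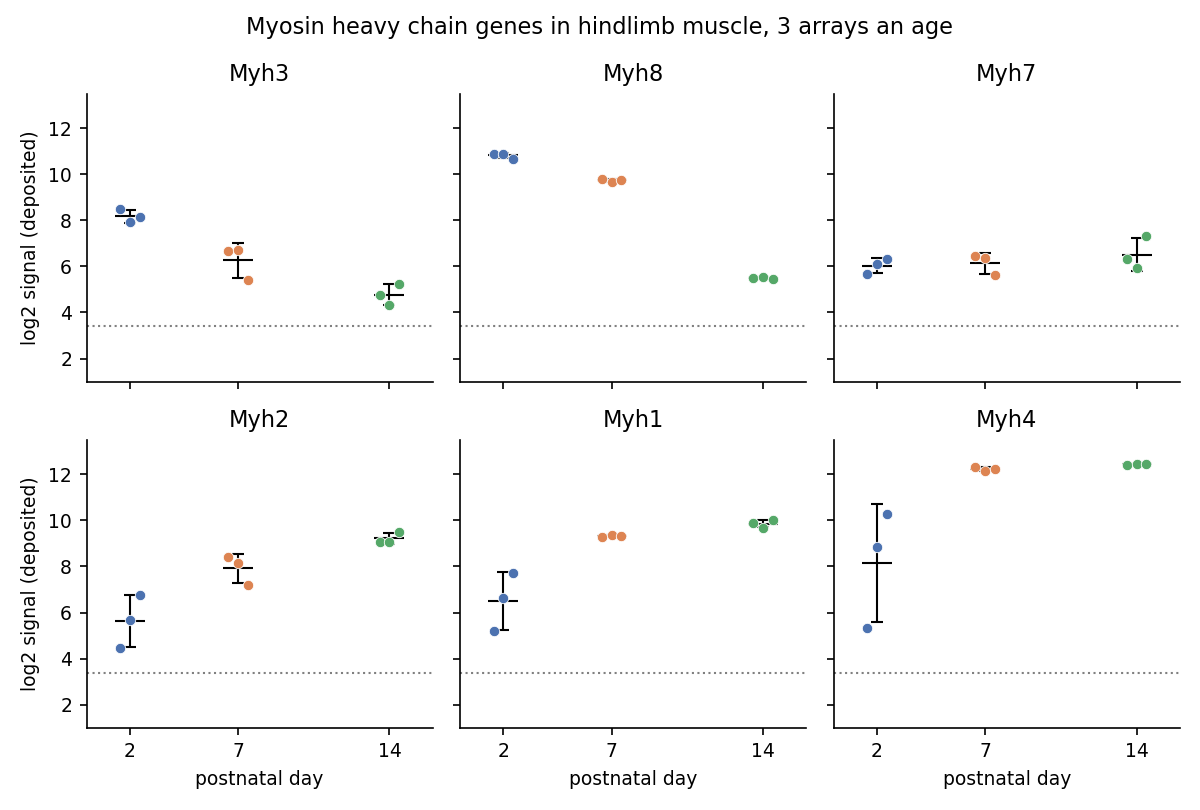
Log2 signal of 6 myosin heavy chain genes (vertical axis) at postnatal day 2, 7 and 14 (horizontal axis), with points for arrays, bars for means, error bars for SD (n = 3) and a dotted line at the 95th percentile of receptor genes (3.40). Myh8 went from 10.82 ± 0.12 at P2 to 9.74 ± 0.06 at P7 and 5.50 ± 0.06 at P14.

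Of the 15 measured adult fast isoforms, 6 rose, 0 fell and 9 were not called by limma, with 10 rising when adjusted over the list alone and 10 at an unadjusted p under 0.05 (median log2 0.73, camera adjusted p = 8.53e-14, 0.310 with an estimated correlation, marked estimated below). The developmental isoforms had 4 falls among 7 genes, over all genes and over the list alone, including cardiac troponin T (Tnnt2, 2.44-fold lower; lost without P7 replicate 3, adjusted p = 0.0610), and a median of -1.05 (adjusted p = 0.000238, estimated 0.363). The sarcomere scaffold list was at 0.29 (adjusted p = 2.92e-05, estimated 0.405), with 2 of 18 genes rising (3 over the list alone). Excitation-contraction coupling was at 0.41 (adjusted p = 2.46e-06, estimated 0.310), with 1 of 18 rising over all genes, and 7 rising and 1 falling over the list alone. The adult acetylcholine receptor subunit Chrne, which replaces the fetal subunit Chrng at the neuromuscular junction, rose 2.74-fold (log2 1.46 ± 0.18, adjusted p = 0.00462). Chrng itself had a change of -1.14 ± 0.24 and was not called (adjusted p = 0.0556). The muscle ankyrin repeat gene Ankrd23 rose 5.26-fold. The kelch gene Klhl33 rose from 3.37 ± 0.63 at P2 to 5.94 ± 0.17 at P7, and the methyltransferase gene Mettl21e fell from 5.58 ± 0.73 to 2.64 ± 0.48. Each has 1 value under the receptor level of 3.40, so no fold is given, here or for later genes of that kind.

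The cell cycle list had a median log2 change of -0.49 (camera adjusted p = 2.08e-16, estimated 0.405), yet limma called 0 of 44 members over all genes, with 27 at an unadjusted p under 0.05 and 10 falling adjusted over the list alone. Mki67, a marker of dividing cells, had a value of -0.48 ± 0.21 (adjusted p = 0.358). Cks2, a cell cycle gene outside the list, was called and fell from 5.21 ± 0.41 to 3.36 ± 0.48, under the receptor level (adjusted p = 0.0112; lost without P7 replicate 1 or 3, up to 0.0667). Imprinted growth genes had a median of -0.39 (adjusted p = 1.4e-05, estimated 0.310), with 1 of 15 falling over all genes, 6 over the list alone, and Igf2 at -0.21 ± 0.17, not called. Interstitial matrix was at -0.40 (adjusted p = 9.32e-10, estimated 0.432; -0.26 without P2 replicate 3). Its fibrillin Fbn2, an elastic fibre protein made mostly before birth, was 3.18-fold lower (log2 -1.67 ± 0.17), 2 of 27 members fell over all genes and 11 over the list alone, and the collagens Col1a1 (-0.26) and Col3a1 (-0.05) were not called. Mast cell carboxypeptidase Cpa3 was 3.54-fold lower (log2 -1.82 ± 0.25, adjusted p = 0.00761). Pax7 (-0.12), Myod1 (0.34) and Myog (-0.07), which mark satellite cells and differentiating myoblasts, were not called.

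Oxidative phosphorylation had a median of 0.25 (adjusted p = 2.74e-09, estimated 0.473; 0.10 without P2 replicate 1), with 0 of 61 members called by limma over all genes, 3 rising over the list alone and 16 at an unadjusted p under 0.05. Glycolysis and glycogen was at 0.26 (adjusted p = 0.000458, estimated 0.473; 0.17 without P2 replicate 1), with 2 members rising over the list alone. The circadian clock list was at 0.19 (adjusted p = 0.000548, estimated 0.310; 0.30 without P2 replicate 3, and also moved by P7 replicate 2), with 1 rising over all genes and 5 over the list alone. Among markers of other cell types, the endothelial list was at 0.24 (adjusted p = 0.0130, estimated 0.691), but 0.12 without P2 replicate 1 (adjusted p = 0.346) and 0.43 without P2 replicate 3. It also lost its call without P2 replicate 2 or P7 replicate 1, and P7 replicate 2 moved its median by over 1.5 times. Tendon was at -0.35 (adjusted p = 0.0426, estimated 0.535; -0.20 and 0.493 without P7 replicate 3; also lost without P2 replicate 2 or 3). Cartilage and bone was at -0.38 (adjusted p = 0.0490, estimated 0.719; 0.11 without P2 replicate 2 and -0.77 without P2 replicate 3; adjusted p = 0.607 without P7 replicate 3; also lost without P14 replicate 1). Neutrophil precursor markers were at -0.43 and the 4 erythroid ones at -0.41, the first not called (adjusted p = 0.0787) and the second not tested.

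Of the 22180 genes 73 changed from P2 to P7 (0.329%; 41 higher and 32 lower), 59 of them by at least 2-fold, with 2847 at an unadjusted p under 0.05 against 1109 by chance. Centred on array medians the split was 32 higher and 38 lower, and with Xist as a covariate 35 genes were called. Leaving out 1 array gave 44 (P2 replicate 1), 206 (P2 replicate 2), 154 (P2 replicate 3), 20 (P7 replicate 1), 27 (P7 replicate 2), 11 (P7 replicate 3), 41 (P14 replicate 1), 42 (P14 replicate 2) or 36 genes (P14 replicate 3). Of 25 named genes called, 7 kept the call with any array left out, namely Pvalb, Klhl33, Ankrd23, Mettl21e, Cpa3, Fbn2 and Chrne. Of 38 lists camera called 13, 7 higher and 6 lower, and 10 of the 13 kept the call with any array left out; with an estimated correlation it called 0 (5 at an unadjusted p under 0.05, smallest adjusted p = 0.310), and fry called 3. In 4 lists the median, mean and test differed in sign, and camera called none of these (myogenic regulators, basement membrane, splicing regulators and adipocyte markers).

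The second comparison asked what changed in the second postnatal week, from P7 to P14. The perinatal myosin fell further. Myh8 was 18.9-fold lower at P14 (9.74 ± 0.06 at P7 and 5.50 ± 0.06 at P14, SD, n = 3; log2 -4.24 ± 0.16, SE; adjusted p = 2.26e-09). Sarcolipin (Sln), a brake on the calcium pump of the sarcoplasmic reticulum, was 18.9-fold lower (9.61 ± 0.22 and 5.37 ± 0.85; log2 -4.24 ± 0.34). The precursor signal of Mir380 and Mir376b, which lie in the imprinted region between Dlk1 and Dio3, was 8.55-fold and 8.39-fold lower, and that of their neighbour Mir495 fell from 6.37 ± 0.12 to 3.05 ± 0.30, under the receptor level. Stfa2l1, a stefin, fell from 5.21 ± 1.16 to under that level, but lost its call without any P14 array, P7 replicate 1 or P7 replicate 3 (adjusted p up to 0.150, without P7 replicate 3). The largest rises were in Slc25a25, a mitochondrial carrier (5.80-fold, log2 2.53 ± 0.18), Klhl33 (4.66-fold), the phosphorylase kinase subunit Phka1 (4.40-fold), the muscle ubiquitin ligase Fbxo40 (4.22-fold), Angptl7 (4.12-fold) and Gadd45g (4.08-fold).

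Imprinted growth genes are in many cases expressed in fetal tissue and silenced after birth. Of 15 members 8 fell over all genes and 11 adjusted over the list alone, with a median of -0.78 (camera adjusted p = 9.74e-20). Dlk1 was 3.91-fold lower (log2 -1.97 ± 0.17), Rian 3.50-fold, Meg3 2.66-fold and Plagl1 2.62-fold; Igf2 was 1.88-fold lower but lost its call without P14 replicate 2 or P14 replicate 3 (adjusted p up to 0.0626). Of 42 microRNA genes of the region between Dlk1 and Dio3 with signal above the receptor level, a set chosen after its values were seen, 42 fell, with a median of -2.30 (quartiles -2.56 and -2.12). For 8 of them the P14 mean is under that level, so the size of their own falls is uncertain. The median of the other 34 was -2.29 (4.88-fold lower), and 41 of the 42 fell without any 1 of the P7 or P14 arrays. Their median from P2 to P7 was -0.18 and limma called 0 of them there (3 at an unadjusted p under 0.05), and 27 had a called difference between the intervals (15, 13 and 14 without P7 replicates 1, 2 and 3, and 17 without P14 replicate 2). Of 9 other genes of the region above that level 8 fell (median -1.81), and the 123 microRNA genes elsewhere had a median of -0.081.

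**Figure D2:**
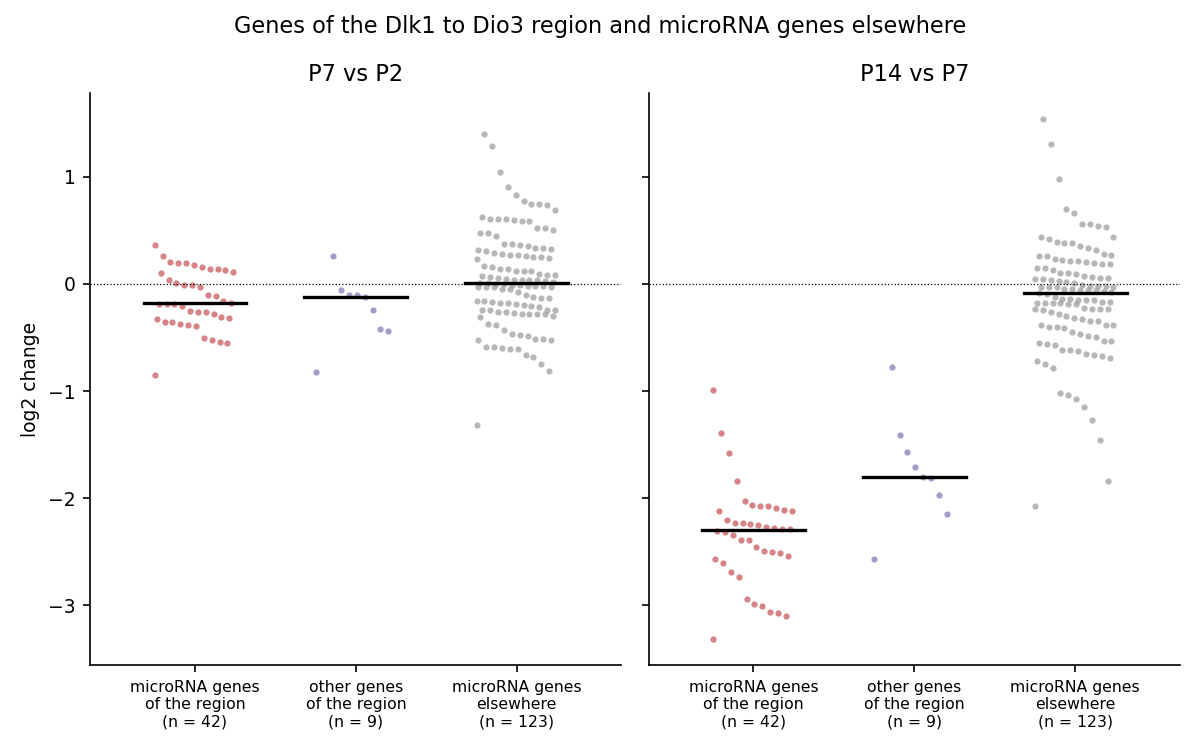
Log2 change (vertical axis) from P2 to P7 (left) and from P7 to P14 (right) of microRNA genes of the region between Dlk1 and Dio3 (n = 42), other genes of the region (n = 9) and microRNA genes elsewhere (n = 123), all above the receptor level. Points are genes, horizontal bars are medians and the dotted line is no change. The medians from P7 to P14 were -2.30, -1.81 and -0.081.

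The cell cycle list had a median of -0.52 (adjusted p = 9.74e-20, estimated 0.246), 6 of 44 falling over all genes and 22 over the list alone; Mki67 was 2.26-fold lower (log2 -1.18 ± 0.21) and thymidylate synthase Tyms 1.97-fold. Interstitial matrix was at -0.34 (adjusted p = 2.89e-07, estimated 0.354; -0.21 without P7 replicate 1), with 2 of 27 members falling over all genes, and 5 falling and 1 rising over the list alone. Periostin (Postn) was 2.48-fold lower and Fbn2 2.47-fold, and Col1a1 (-0.47) and Col3a1 (-0.52) were not called. Markers of neutrophil precursors moved with these lists (-0.97, adjusted p = 5.6e-05, estimated 0.316), with 0 of 8 called by limma over all genes, 2 falling over the list alone and 6 at an unadjusted p under 0.05, and the erythroid markers had a median of -0.70. Cartilage and bone was at -0.53 (adjusted p = 0.00358, estimated 0.403; median -0.35 and no call without P7 replicate 1, and -0.80 without P7 replicate 3). Ribosomal proteins had a small negative median (-0.14, adjusted p = 0.00487, estimated 0.246; 0.0685 without P7 replicate 2).

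Some transcripts for energy supply rose, but the calls of their lists were lost with an estimated correlation. Glycolysis and glycogen had 6 rises and 1 fall among 18 genes, 14 and 1 over the list alone (median 0.69, adjusted p = 4.49e-13, estimated 0.199), including hexokinase Hk2 (2.59-fold, log2 1.38 ± 0.20), the branching enzyme Gbe1 (2.23-fold) and glycogenin Gyg (1.97-fold). The member that fell was Fbp2 (-0.72 ± 0.17), a gluconeogenic enzyme that works against glycolysis, named here after its value was seen; its call ended without any P7 or P14 array (adjusted p up to 0.144, without P14 replicate 3). Oxidative phosphorylation had 9 rises among 61 genes, 37 over the list alone (median 0.55, adjusted p = 9.74e-20, estimated 0.246); Uqcrc1 (2.00-fold) and Ndufs1 (1.85-fold) both lost the call without P14 replicate 1 (0.0517). The tricarboxylic acid cycle had 4 rises among 14 genes, 12 over the list alone (median 0.63, adjusted p = 2.73e-09, estimated 0.0776). Over the list alone 1 member fell, Idh2, which was not called over all genes (log2 -0.65, adjusted p = 0.0936) and was named after its value was seen. Fatty acid oxidation had 3 rises among 23 and 11 over the list alone (0.45, adjusted p = 1.38e-08, estimated 0.246), among them the carnitine carrier Slc25a20 (2.07-fold). Immediate early genes, which respond to stimulation within minutes, had a median of 0.38 (adjusted p = 3.09e-06, estimated 0.0692), with Nr4a1 higher (5.79 ± 0.28 at P7 and 7.79 ± 0.13 at P14, SD, n = 3) and Dusp1 2.60-fold higher (2 of 12 over all genes and 5 over the list alone). That list was fixed as a sign of tissue handling, which the labels do not describe, so its rise is not attributed to age. The clock gene Per1 rose 2.86-fold and its list was at 0.20 (adjusted p = 0.00793, estimated 0.258; 0.12 without P7 replicate 2). The time of day at collection was not part of any fit, so its share in the clock changes was not tested for any pair of ages. Protein breakdown and autophagy was at 0.33 (adjusted p = 0.0114, estimated 0.246; 0.0803 without P14 replicate 3).

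The adult fast list had a positive median (0.53, adjusted p = 9.15e-07, estimated 0.246), although limma called 0 of 15 over all genes (9 at an unadjusted p under 0.05) and 9 rose over the list alone. Myh4 (0.19 ± 0.79), Myh1 (0.53 ± 0.42), Myh2 (1.30 ± 0.43) and Myh7 (0.37 ± 0.31) were not called, and for none of these 4 was the difference between the intervals called (adjusted p = 0.443, 0.346, 0.788 and 0.940). The developmental isoforms were at -0.45 (adjusted p = 0.0107, estimated 0.316), with 3 falls. Myh3 was 2.85-fold lower (lost without P7 replicate 1 or 2 or P14 replicate 1 or 2, adjusted p up to 0.130, without P14 replicate 2), whereas cardiac actin Actc1, the fetal actin of skeletal muscle, rose 2.09-fold (lost without P7 replicate 2 or 3 or P14 replicate 1 or 2, up to 0.143). The scaffold list was at 0.28 (adjusted p = 0.00710, estimated 0.401). Excitation-contraction coupling was at 0.30 (adjusted p = 0.00793, estimated 0.316), with 3 rises, among them the chloride channel Clcn1 (1.94-fold), and 2 falls, Sln and the ryanodine receptor Ryr3 (2.60-fold lower), a form found in young muscle. Cardiac calsequestrin Casq2 was 2.47-fold lower. Chrng (-0.31), Pax7 (-0.27), Myod1 (0.23) and Myog (-0.18) were not called.

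Of the 22180 genes 538 changed from P7 to P14 (2.43%; 382 higher and 156 lower), 268 of them by at least 2-fold, with 3248 at an unadjusted p under 0.05. With cyclic loess the split was 277 higher and 195 lower. Leaving out a P7 array gave 316 (replicate 1), 296 (replicate 2) or 276 genes (replicate 3), and leaving out a P14 array 220, 214 or 229 for replicates 1, 2 and 3. Of 56 named genes called, 29 kept the call with any array left out and 27 lost it at least once. Only some of these losses are marked above, so a call without such a mark need not be stable. Camera called 17 of 38 lists, 10 higher and 7 lower, 14 of which kept the call with any array left out; with an estimated correlation it called 1, imprinted growth genes (adjusted p = 0.0450; lost without P2 replicate 2 or any P7 or P14 array, up to 0.121 without P7 replicate 1), and fry called 10. In 2 lists, antigen presentation and macrophage markers, the median, mean and test differed in sign without a call.

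The third comparison, P14 with P2, spanned the series and so asked what both weeks amounted to. Myh8 was 39.9-fold lower at P14 (10.82 ± 0.12 at P2 and 5.50 ± 0.06 at P14, SD, n = 3; log2 -5.32 ± 0.16, SE; adjusted p = 9.19e-11), Sln 27.0-fold lower and Myh3 10.6-fold lower. Klhl33 rose from 3.37 ± 0.63, under the receptor level, to 8.16 ± 0.16, Pvalb rose 22.6-fold (6.24 ± 1.23 and 10.74 ± 0.10), Myh4 19.4-fold, Ankrd23 16.6-fold, the noncoding transcript Nctc1 14.3-fold, Myh2 12.0-fold and Myh1 10.1-fold, whereas Myh7 (0.48 ± 0.31) was not called. Among the falls was the Dlk1 to Dio3 region's Mir379 (10.7-fold lower), and bone sialoprotein (Ibsp, from 6.84 ± 1.12 to 2.40 ± 0.26) and Stfa2l1 (from 5.84 ± 2.45) fell to under the receptor level.

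Of 15 adult fast isoforms 12 rose over all genes and 14 over the list alone (median 1.44, camera adjusted p = 2.29e-15, estimated 0.0969), among them the myosin binding protein Mybpc2 (6.71-fold) and calsequestrin Casq1 (2.72-fold). Of the developmental isoforms 4 fell and 2 rose (-1.74, adjusted p = 0.00220, estimated 0.230). Those that rose were the actins Actc1 (1.23 ± 0.23, named after its value was seen) and Acta2 (1.82-fold; lost without P14 replicate 2, adjusted p = 0.0557), the second also a smooth muscle marker. Slow isoforms had a median of -0.27 and were not called (adjusted p = 0.166), with Casq2 2.92-fold lower. In the scaffold list 10 of 18 genes rose (0.55, adjusted p = 3.66e-06, estimated 0.180), led by Xirp2 (5.02-fold). Excitation-contraction coupling had 12 rises and 2 falls (0.97, adjusted p = 5.51e-07, estimated 0.104), led by Clcn1 (3.50-fold) and Stac3 (3.51-fold), with Sln and Ryr3 (4.51-fold lower) falling. The dystrophin complex (0.07, adjusted p = 0.803) and neuromuscular junction (-0.17, adjusted p = 0.436) lists were not called, and the sign of the first median changed between scalings. Their members went both ways, with sarcoglycan Sgca 2.43-fold higher, Chrne 4.69-fold higher, Chrng 2.74-fold lower and the adhesion molecule Ncam1 2.92-fold lower.

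Myogenic regulators had a median of 0.07 (adjusted p = 0.585), which also changed sign between scalings, with 3 rises, such as Eya1 (2.22-fold), and 3 falls, such as Myf5 (2.17-fold lower), an early determination factor. Pax7 (-0.39 ± 0.28), Myod1 (0.57 ± 0.20) and Myog (-0.24 ± 0.17) were not called. Myoblast fusion was at -0.18 (adjusted p = 0.0229, estimated 0.123; 0.0554 without P2 replicate 3) with 3 falls. The Notch pathway was not called (median 0.06, adjusted p = 0.782; its mean and test were negative). Of 44 cell cycle genes 35 fell over all genes and 41 over the list alone (-0.99, adjusted p = 2.86e-30, estimated 0.123), including the topoisomerase Top2a (3.31-fold lower) and Mki67 (3.16-fold lower). Neutrophil precursor (median -1.32) and erythroid (-1.18) markers were lower too, while lymphocyte (-0.14) and macrophage (-0.20) markers were not called. With the level of neutrophil and erythroid markers as a covariate, the cell cycle median was -0.55 and 10 members were called. That test was chosen after the values were seen. Of 15 imprinted growth genes 12 fell (-1.18, adjusted p = 2.33e-17, estimated 0.0648), with Dlk1 6.92-fold, Plagl1 4.84-fold and Igf2 2.18-fold lower. The insulin-like growth factor axis was at -0.50 (adjusted p = 0.0383, estimated 0.182; lost without P2 replicate 3, at 0.115, and without P14 replicate 2, with a median of -0.38), with 4 falls, such as the receptor Igf1r (1.97-fold lower), and 3 rises, of the binding proteins Igfbp5, Igfbp6 and Igfbp7. These 3 were named after their values were seen, and each lost its call without P2 replicate 1 or P14 replicate 3 (adjusted p up to 0.130, for Igfbp6). Interstitial matrix had 12 falls among 27 (21 over the list alone; -0.67, adjusted p = 1.04e-13, estimated 0.182), with Fbn2 7.85-fold and Postn 3.75-fold lower and Col1a1 (-0.73) and Col3a1 (-0.57) not called. Basement membrane was not called (-0.04, adjusted p = 0.573).

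Of 61 oxidative phosphorylation genes 43 rose over all genes and 51 over the list alone (0.84, adjusted p = 4.21e-25, estimated 0.123), led by the muscle cytochrome oxidase subunit Cox7a1 (4.50-fold). The tricarboxylic acid cycle had 12 rises among 14 (0.83, adjusted p = 9.01e-09, estimated 0.0969) and 1 fall, the NADP-dependent Idh2 (2.34-fold lower). In fatty acid oxidation 7 of 23 rose (0.36, adjusted p = 7.73e-05, estimated 0.251), Ucp3 most (4.42-fold), and in glycolysis and glycogen 16 of 18 (0.94, adjusted p = 1.04e-13, estimated 0.105), including Phkg1 (5.07-fold) and Phka1 (4.97-fold). Ribosomal proteins had 10 falls and 1 rise among 56 (-0.22, adjusted p = 0.000207, estimated 0.123), with Rps4x 2.36-fold lower and Rpl34 2.13-fold higher. Ribosome biogenesis was not called (0.26, adjusted p = 0.436) although nucleophosmin Npm1 was 2.24-fold lower. Protein breakdown and autophagy (0.25, adjusted p = 0.119) and splicing regulators (-0.16, adjusted p = 0.865) were not called. The ubiquitin ligase Trim63 was 3.04-fold higher, Mbnl1 1.84-fold higher and Mbnl3, its fetal relative, fell from 3.87 ± 0.36 to 2.87 ± 0.06, under the receptor level. In the circadian clock list 7 of 15 genes rose (0.68, adjusted p = 1.24e-05, estimated 0.104), led by Bhlhe41 (3.28-fold), and of the immediate early genes 3 of 12 (0.40, adjusted p = 0.000176, estimated 0.0969), led by Nr4a1 (4.20-fold). Neither rise is attributed to age, since time of day at collection and tissue handling were not part of the fit. Interferon-stimulated genes (0.21, adjusted p = 0.585) and antigen presentation (0.04, adjusted p = 0.573) were not called.

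Among markers of other cell types, the endothelial list was at 0.50 (adjusted p = 0.000876, estimated 0.396), with 3 of 12 rising over all genes and 6 over the list alone, such as Flt1 (2.03-fold). Pericyte and smooth muscle markers were at 0.36 (adjusted p = 0.0800), with Rgs5 3.95-fold higher. Neutrophil precursor markers were at -1.32 (adjusted p = 1.24e-05, estimated 0.251; -0.83 without P2 replicate 1 and -2.10 without P2 replicate 2), with 4 of 8 falling over all genes and 8 over the list alone, such as S100a8, from 4.29 ± 1.30 to 2.07 ± 0.22, under the receptor level, and 2 of the 4 erythroid genes fell (median -1.18, not tested as a list). Cartilage and bone was at -1.11 (adjusted p = 0.000176, estimated 0.313; -0.50 without P2 replicate 2), with 3 of 16 falling, among them aggrecan Acan, from 4.84 ± 0.90 to 3.17 ± 0.13, under the receptor level. Fibroblast (0.15, adjusted p = 0.776), tendon (-0.02, 0.585), adipocyte (-0.19, 0.216), macrophage (-0.20, 0.267), lymphocyte (-0.14, 0.540), Schwann cell and nerve (-0.15, 0.267) and epidermis (0.01, 0.573) markers were not called.

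**Figure D3:**
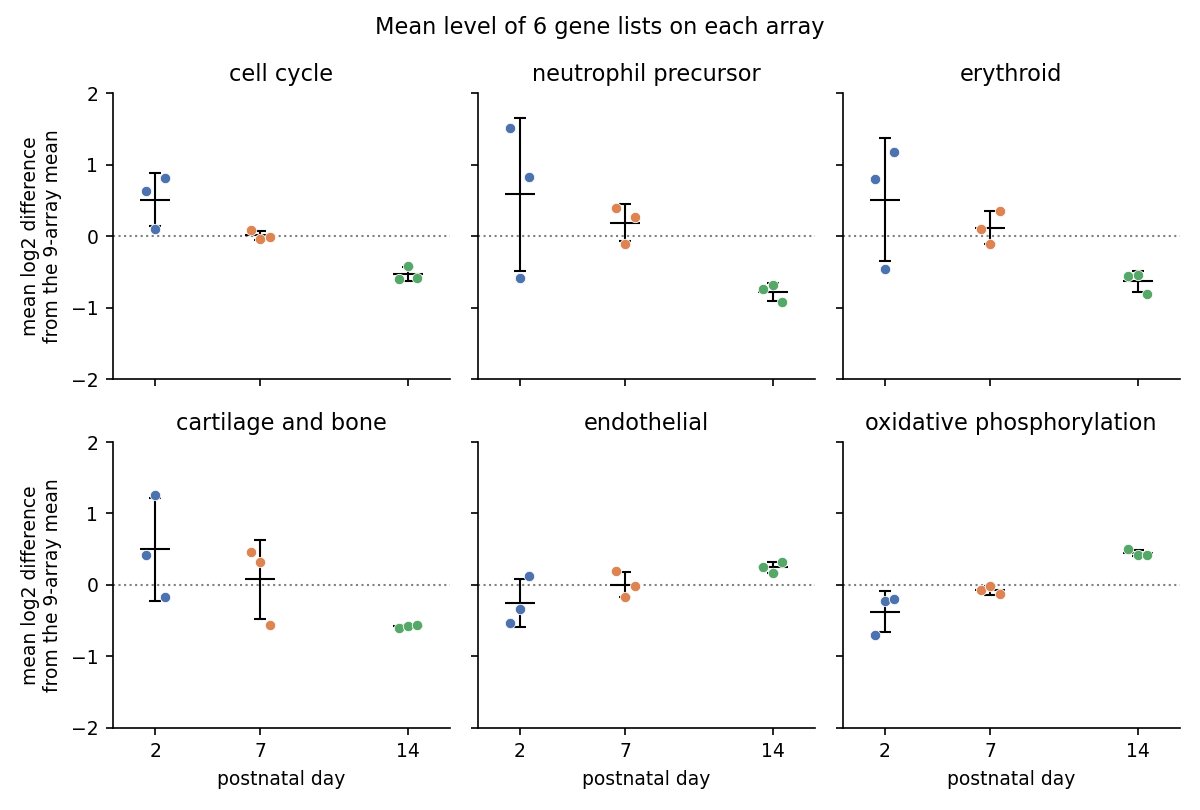
Mean log2 difference from the 9-array mean (vertical axis) of 6 gene lists on each array at postnatal day 2, 7 and 14 (horizontal axis); points are arrays, with the mean and SD of each age (n = 3). Neutrophil precursor markers stood at 1.52, -0.58 and 0.83 on the P2 arrays and at -0.74, -0.68 and -0.92 on the P14 arrays.

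**Figure D4:**
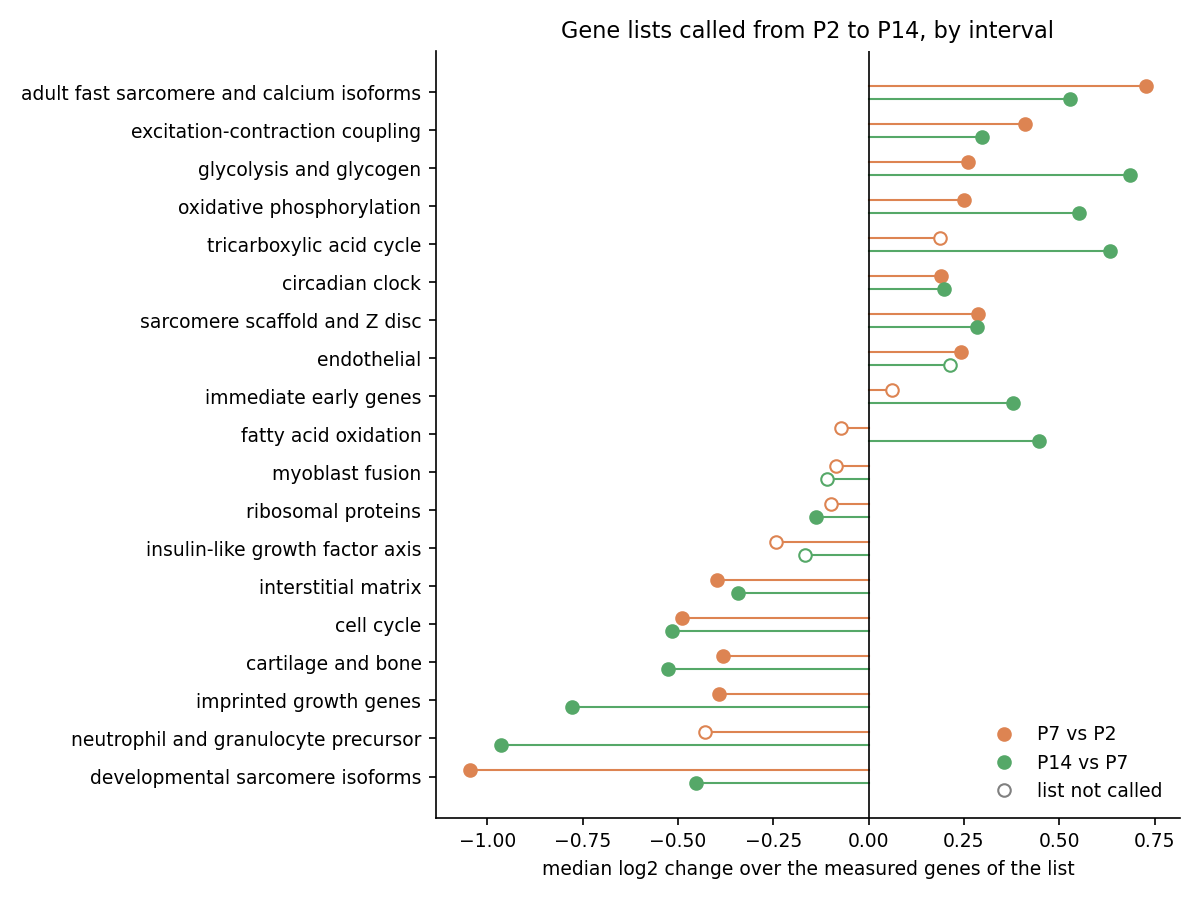
Median log2 change (horizontal axis) of the 19 lists called from P2 to P14 (vertical axis), for P7 against P2 in orange and P14 against P7 in green, with open points where camera did not call the list in that interval. Imprinted growth genes went from -0.39 in the first interval to -0.78 in the second and oxidative phosphorylation from 0.25 to 0.55.

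Of the 22180 genes 2447 changed from P2 to P14 (1470 higher and 977 lower), 908 by at least 2-fold, with 5386 at an unadjusted p under 0.05. Leaving out P2 replicate 1 gave 1584 genes, and leaving out a P14 array 1397, 1373 or 1520 for replicates 1, 2 and 3. Of 118 named genes called, 88 kept the call with any array left out and 30 lost it at least once. Here too only some of the losses are marked in the text. Camera called 19 of 38 lists, 10 higher and 9 lower, 17 of which kept the call with any array left out; with an estimated correlation it called 0 (11 at an unadjusted p under 0.05, smallest adjusted p = 0.0648), and fry called 19.

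Whether the changes differed between the intervals was tested as the later, of 7 days, minus the earlier, of 5 days. The changes were not scaled to a rate per day, so a steady daily rate would also give a difference. The fall of Myh8 was larger after P7 than before (difference -3.16 ± 0.27, SE; adjusted p = 0.000230), and Mir376b (-3.27 ± 0.38) and Mir379 (-2.71 ± 0.33) fell after P7 beyond their earlier change. Mir495 had a called difference too, but its P14 value is under the receptor level, so the size of its later fall is uncertain. Slc25a25 rose more after P7 (2.40 ± 0.32), and Mettl21e had a called difference (3.84 ± 0.53) that is not interpreted, since its P7 value is under the receptor level. These 6 calls held with any array left out, whereas those of Sln, Mir380, Rian, Gadd45g, Nr4a1, Phka1 and Per1 each ended without at least 1 of the P7 arrays (adjusted p up to 0.233, for Phka1 without P7 replicate 3). None of the list calls that follow held with an estimated correlation, where the adjusted p was 0.372 or more. Imprinted growth genes were lower after P7 by the preset test (median of the difference -0.51, camera adjusted p = 9.45e-06), and fatty acid oxidation (0.50, 8.58e-05) and immediate early genes (0.51, 0.00134) were higher, all with any array left out. The tricarboxylic acid cycle (0.39, 0.00324) was called except without P2 replicate 2 (0.0526). Glycolysis and glycogen (0.36, 0.00338) lost its call without P2 replicate 2 or P7 replicate 3 (0.0534, median 0.21, without the latter). Oxidative phosphorylation (0.23, 0.0227) lost it without any of 5 arrays (0.253 without P2 replicate 2), with a median of 0.39 without P2 replicate 1, and tendon (0.53, 0.0381) without any of 4 (0.656 without P7 replicate 3). The cell cycle list had a median difference of -0.05 (adjusted p = 0.495) and the adult fast list of -0.31 (0.0586). In 10 lists the median, mean and test of the difference were not all of one sign, and camera called none of those.

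In all, 43 genes had a called interval difference (8 higher and 35 lower; 1801 at an unadjusted p under 0.05), with 28 without P7 replicate 1, 18 without P7 replicate 2, 21 without P7 replicate 3 and 23 without P14 replicate 2. The F-test over the 3 ages called 1827 genes (8.24%), with 874, 845 and 899 when P14 replicates 1, 2 and 3 were left out. In both intervals 10 genes rose, Chrne, Clcn1, Ankrd23, Klhl33 and Xirp2 among them, and 12 fell, Myh3, Myh8, Myl4, Fbn2 and Plagl1 among them, where independent lists would share 0.706 and 0.225. Leaving out an array gave 3 and 2 (P7 replicate 1), 4 and 5 (P7 replicate 2), 3 and 1 (P7 replicate 3), 2 and 8 (P14 replicate 1), 2 and 8 (P14 replicate 2), 3 and 8 (P14 replicate 3), 10 and 7 (P2 replicate 1), 23 and 32 (P2 replicate 2) or 32 and 12 (P2 replicate 3). Only 3 of the 22, Klhl33, Nctc1 and Fbn2, kept both calls with any array left out. Another 2 rose and then fell, Defb23 and Gm2837, both with signal under the receptor level and named after their values were seen. Simulated unchanged groups that share the P7 arrays gave a mean of 0 genes in the same direction and 0.02 in opposite directions. With no gene changed almost none is called, so these simulations cannot tell whether the overlap exceeds that of unrelated changes. The log2 changes of the intervals correlated at 0.0276 across genes, which are not independent, against -0.499 in those simulations, where the shared P7 arrays enter with opposite sign. Real changes that are unrelated between the intervals also bring the correlation nearer to 0, so this gap alone does not show a shared direction. Unrelated changes would not move the covariance, which was 0.00294 against a simulated mean of -0.0220. The variance of changes beyond sampling was 0.0334 and 0.0796 in the intervals and 0.168 from P2 to P14. Unrelated changes would make the last the sum of the others. These values argue against wholly unrelated changes, though the covariance was not computed with arrays left out. Of the 2447 genes changed from P2 to P14, 1921 were called in neither interval.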

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

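Xist as a covariate, the level of neutrophil and erythroid markers as a covariate and the filter at the receptor genes were chosen after the data were seen; the other alternatives were planned.

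Of 199 calls of named genes, centring on array medians kept 196, quantile normalization 191, cyclic loess 192, the mean of a gene's probe sets 192, array weights 192, a trended prior 198, a trended and robust prior 190, the Xist covariate 181, only the 2 ages compared 175, the marker covariate 119 and no moderation 118. Of 198 such calls in genes that passed, the filters at the median of all probe sets and at the receptor genes each kept 198. Among 49 list calls, centring kept 47, quantile normalization 48, cyclic loess 48, camera on ranks 44, fry 28 and the estimated correlation 1. The list calls kept were 41 with the marker covariate, 43 with each of the filters at the median and the receptor genes, 46 with the Xist covariate and 47 with array weights. No called gene among those named and no called list reversed under the scalings. Medians of lists not called changed sign for the dystrophin complex and myogenic regulators in all 3 pairs of ages, basement membrane from P2 to P7 and antigen presentation from P7 to P14. The marker covariate reversed 1 gene, Ltf, at 0.091 against -1.21. Ltf is in the marker list that made the covariate, so its construction removes the change.

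Counts from P2 to P7 (73) moved to 111 with cyclic loess, 159 with a trended prior and 159 with a trended and robust prior, 9 without moderation, 35 with the Xist covariate, and 12 with only the 2 ages compared. Filters that leave fewer genes to adjust over gave 173 at the median of all probe sets, 119 at the 25th percentile and 175 at the receptor genes, and all probe sets, which are more tests, gave 6. From P7 to P14 (538) the counts moved to 809 and 814 with the filters at the median and the receptor genes, 208 without moderation, 1221 with array weights, 1051 with only the 2 ages compared and 272 over all probe sets. From P2 to P14 (2447) they moved to 1371 without moderation and 1028 with the marker covariate, of which 767 were among the 2447. The interval difference (43) moved to 3 without moderation, 24 with the Xist covariate and 1 over all probe sets, and the F-test (1827) to 636 without moderation, 658 with the marker covariate and 1003 over all probe sets. The cause of these moves was not tested. The filters and the use of all probe sets also changed the values behind the moderation, besides the number of tests. Counts over all probe sets are of probe sets, not of genes.

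The fit with the replicate number as a replicate block gave 61, 458 and 2320 genes for the 3 pairs of ages, 33 for the interval difference and 1635 for the F-test, with 186 of 199 named calls and 48 of 49 list calls kept. Correlations of the arrays' deviations within a replicate number were -0.0286 to 0.0565, so they gave no sign that the numbers pair the samples. They cannot show whether samples of the same number were handled together.

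Leaving out 1 array gave 11 to 206 genes for P7 against P2, 214 to 794 for P14 against P7, 1373 to 2611 for P14 against P2, 18 to 44 for the interval difference and 845 to 2139 for the F-test. Named calls were kept in 1481 of 1791 cases and list calls in 426 of 441, and 1 list reversed, cartilage and bone from P2 to P7, with medians from -0.77 to 0.11 (0.11 without P2 replicate 2, against -0.38); the fit then rests on fewer arrays. A filter on probe set identifier endings was not run, since the identifiers carry none. Signal over background limits the rest: 13420 of 22180 genes (60.5%) had a mean above the receptor level of 3.40 in at least 1 age, and a change in the others is hard to see. On simulated data of this size, 79% of 100 genes shifted by 1 and 100% of 100 shifted by 2 were called, with 11 false among 190 calls. Simulated genes were independent, each with the same spread at all ages. The real spread was wider at P2 (median SD 0.251) than at P14 (0.163), so these shares need not hold for the real arrays.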

Other observations

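The gene groups of the next paragraphs, the tests by array weights, by the marker level as a covariate and within ages, and by endothelial markers, and the covariates and the receptor filter, were chosen after the results were seen; the other tests here were planned before their result.

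Of 12 genes of mast cells, 4 fell from P2 to P7 over all genes and 7 adjusted over the list alone (median -0.78, camera adjusted p = 2.88e-11, and 0.00456 with an estimated correlation). Besides Cpa3, the tryptase Tpsb2 was 2.85-fold lower (log2 -1.51 ± 0.21, SE) and the chymase Cma1 2.50-fold lower (-1.32 ± 0.18), each with any array left out. From P7 to P14 the median was -0.25 (-0.38 to -0.20 with 1 array left out), with 3 falling over the list alone. Its adjusted p was 0.000794 by camera, and 0.0363 with an estimated correlation (0.113 without P2 replicate 1). The difference between the intervals was not tested for this list. From P2 to P14 8 of 12 fell, with Cpa3 6.54-fold, Cma1 3.76-fold and Mcpt4 3.07-fold lower. The Asb family, which supplies substrate receptors of ubiquitin ligases, had 10 rises and 0 falls among 18 genes from P2 to P14 (11 at an unadjusted p under 0.05 by limma; median 0.76, adjusted p = 0.00619 with an estimated correlation), among them Asb14 (6.20-fold), Asb16 (4.05-fold), Asb15 (2.95-fold) and Asb5 (2.44-fold). For the mast cell and Asb lists these calls from P2 to P14 held with any array left out. The camera p-values of the lists in this paragraph and the next were adjusted over these lists alone, not over the planned lists. As these lists were also chosen after the results were seen, their p-values overstate the evidence. They cannot be set beside those of the planned lists, with the preset or the estimated correlation.

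From P2 to P14, of 13 tubulins 6 fell, including Tuba1a (2.41-fold lower), Tubb6 (2.54-fold) and Tubb5 (2.14-fold), and Tuba8 rose 5.60-fold (list median -0.52, adjusted p = 0.00227, and 0.206 with an estimated correlation). With 1 array left out the list median was -0.69 to -0.34. The elongation factor Eef1a1 was 2.11-fold lower while its muscle form Eef1a2 rose 4.14-fold. The muscle ribosomal protein Rpl3l rose 4.21-fold, and the general form Rpl3 was not called (-0.48 ± 0.27, adjusted p = 0.297). Mitochondrial ribosomal proteins had 21 rises among 68 (39 over the list alone; median 0.50, adjusted p = 2.79e-13, and 0.0341 with an estimated correlation, 0.0742 without P2 replicate 2). Proteasome subunits had 3 rises among 38 (median 0.24, adjusted p = 0.00113, and 0.206 with an estimated correlation).

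Xist had values of 2.42, 2.10 and 8.80 on the P2 arrays, 8.43, 3.26 and 8.76 at P7 and 7.97, 3.09 and 2.48 at P14, and the Y-linked Eif2s3y values of 6.04, 5.74 and 2.15, 1.91, 6.26 and 2.07, and 1.81, 6.12 and 6.15, in the order of the replicates. Xist thus lay above the receptor level and Eif2s3y under it on 1 of 3 arrays at P2, 2 of 3 at P7 and 1 of 3 at P14. The reverse held on the other arrays. By these genes the sexes were not balanced across the ages, and the labels give no sex. With Xist as a covariate 35 genes were called from P2 to P7 against 73, and 24 for the interval difference against 43; whether sex or the degree of freedom spent is behind this was not tested.

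Other splits of the same arrays were counted for each result. For each pair of ages 1 of 10 splits, the real one, gave as many genes (73, 538 and 2447, with 1, 0 and 0 the highest of the others), and 10 splits are too few for a share under 0.05. For the F-test 1 of 100 drawn splits, the real one, gave 1827 genes and the highest other 1071. That share is under 0.05, which argues against a chance division of the arrays but cannot tell age from anything that changed with it. For the interval difference 4 of 100 gave at least the real 43 genes, a share under 0.05, and the highest other gave 1539, with the 3 P2 arrays in the middle, which points to a structure of the samples by age. The remaining splits of the 4 gave 253 and 52 and mixed P2 and P7 arrays in the middle. As mixed ages widen the spread within groups, these splits test for an effect of age at all, and neither their share nor 1539 shows that the intervals differ.

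Fewer genes changed from P2 to P7 (73) than from P7 to P14 (538). The wider spread among the P2 arrays would hide changes without making them smaller, but the variance of log2 changes beyond sampling before P7 was 0.419 of that after it (0.133 without P2 replicate 1 to 0.643 without P2 replicate 2), which argues against it as the whole cause. Array weights gave 22.6 times as many calls after P7 as before, but the weights were higher on the P14 arrays (1.38 to 1.78) than on the P2 ones (0.513 to 0.768), which adds calls after P7 by itself, so a single spread estimate shared by the 3 ages stays open. The later interval is also the longer, at 7 against 5 days, and age as the biological explanation stays open and untested.

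The microRNA genes between Dlk1 and Dio3 fell from P7 to P14 (median -2.30). A shift of all microRNA probe sets is argued against by the 123 microRNA genes elsewhere, whose median was -0.081 (quartiles -0.38 and 0.14). Lower RNA over much of the locus is a candidate explanation, since 9 of its 9 other genes above the receptor level had a change below -0.5. These 9 are neighbours that may share transcripts, so they are not independent of each other. Dio3 (0.04), Dio3os (-0.09) and 3110009F21Rik (-0.04), also of the locus, are under the receptor level and could not show a fall. Whether less was transcribed or more was broken down, and whether age itself or the makeup of the tissue is behind it, was not tested.

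Cell cycle genes fell from P2 to P14 (median -0.99) together with neutrophil precursor and erythroid markers of blood and marrow cells, which divide. S100a8 was at 4.29 ± 1.30 at P2 and 2.07 ± 0.22 at P14 (SD, n = 3), the latter under the receptor level. With the neutrophil and erythroid marker level as a covariate the median was -0.55 (-1.31 to -0.49 with 1 array left out), 55.9% of the value without it, and 10 members were called against 35. From P7 to P14 it was -0.22 (-0.58 to -0.12 with 1 array left out), 42.7% of the value without it, and 1 member was called against 6. From P2 to P7 it was -0.33 (-0.71 to -0.29), or 66.5%. The covariate made the change smaller, spent a degree of freedom and follows age, and which of these ended the calls was not tested. Within ages the cell cycle and marker levels correlated (r = 0.880, 0.788 without the 2 farthest arrays), and shuffling within ages gave p = 0.162 over 216 orders. The spread lay mostly among the P2 arrays (SD of the neutrophil level 1.07 at P2, 0.26 at P7 and 0.12 at P14). Few orders thus mattered, so the shuffling could hardly reach a small p and decides nothing. As the markers also follow age, their share and an effect of age cannot be told apart. Dilution of all mononuclear cells by growing fibre RNA would lower endothelial markers as well, but their median was 0.50 (0.43 to 0.69 with 1 array left out) and that of pericyte markers stayed at 0.20 to 0.45. Fibroblast markers were at 0.15. Macrophage (-0.20), lymphocyte (-0.14), Schwann cell (-0.15), neutrophil precursor (-1.32) and mast cell (-0.91) medians lay below 0. The lists thus went both ways. They speak only against an equal fall of all these cells, and dilution of some stays open. Fewer dividing muscle cells with age may add to the fall, and this stays untested.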
